A study of Mus musculus with 3 samples.

How the data were processed

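Mouse embryonic stem cells of wild-type genotype were profiled on 3 Agilent 2-colour arrays. Per the labels, 1 array held DNA precipitated with an MBD reagent, which captures DNA that carries 5-methylcytosine (5mC), and the other 2 held DNA immunoprecipitated for 5-hydroxymethylcytosine (5hmC), the oxidised form of 5mC. One of the 5hmC arrays bears the word IVT in its title. The labels do not explain that word, so this array was kept as a group of its own and is called the IVT array. On every array the precipitated DNA was labelled with Cy5 and genomic DNA of the same cells with Cy3, per the labels. Each group therefore held 1 array, nothing in the labels names separate cultures, and no p-value was computed.

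The values used are those the authors deposited in a single table, with 1 row for each of 88736 probes. They are signed numbers with 4 decimals, of the kind a log ratio between 2 channels gives. The software, the normalization, the log base, the centring and the genome build are not given in the sources used here. A log ratio in base 10 would need ratios of up to 1.41e+08, beyond the 65536 levels of a scanner with 16 bits. Base 2 and the natural log could not be told apart, so values are given as deposited, in units of that unnamed logarithm, and no fold enrichment is printed. A higher value likely stands for more precipitated DNA relative to genomic DNA, which rests on the order of the channels in the labels alone. If the sign of all 3 arrays were turned, high and low would change places and the correlations would stay as given. Signal intensities and background flags were not used here, so the depth behind a value is unknown and the number of arrays limits the precision.

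The table names probes by number only, and probe positions and gene annotation were not used here. The comparisons by gene, by gene list and by chromosome that had been fixed before the data were examined could therefore not be run. Probes with consecutive numbers were taken as neighbours, an assumption that was checked by their correlation. Runs of at least 3 consecutive numbers stood in for genes, a choice made after seeing the data, and the gene lists were not used. There were 14403 such runs with 70789 probes, the longest with 23 probes, and no run is named by gene. The preset rule for named items allows, without gene names, at most 2 probe numbers per direction: these are the first probes of the 2 runs with the largest difference each way.

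The 88734 probes with a value on all 3 arrays entered the comparisons, and 2 probes that lack a value on 1 array were left out. For each pair of arrays Pearson's r and Spearman's rho were computed across probes. Probes are not independent replicates. Intervals are 95% intervals from 1000 bootstrap draws of 888 blocks of 100 consecutive probes. They describe the spread over probes within these arrays and not the spread between cultures or hybridisations. High and low probes were the upper and lower 5% of each array. Their overlap was set against that of independent lists. The regional correlation of a pair is the mean correlation between a probe on one array and the next probe on the other, divided by the geometric mean of each array's own neighbour correlation. Variation that is private to a probe cancels from it, whether it is noise or a real difference between neighbours. The regional correlation, the difference between correlations, the split at the median of the 5hmC array, the blocks of probe numbers singled out and the window around the 5mC peak were chosen after seeing the data. For runs, the median over probes was turned into a percentile within each array. A run was held to differ when the percentile of 5mC lay on the same side of both 5hmC arrays and differed from their mean by more than the 5hmC arrays differed from each other. Minimum differences of 20, 30, 40 and 50 percentile points were added after seeing the data, and 50 was the first of them to be tried. The counts were set against 100 shuffles of 5mC over runs and 100 draws of normal values with the observed correlations.

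The procedures were tested on simulated data with the real probe numbers. Over 88734 simulated probes, regional correlations of 0.9, 0.6 and 0.7 were recovered as 0.906, 0.604 and 0.692 for 5mC with 5hmC, 5mC with the IVT array, and 5hmC with the IVT array. Among 14403 simulated runs, 98 of 100 seeded runs with 5mC above 5hmC and 94 of 100 with the opposite order were recovered with a minimum difference of 50 points. All seeded runs had a large shift in opposite directions, so the recovery of smaller differences was not tested. The number of runs called without being seeded is not given here. The simulated signal was constant within a run, which real regions need not be. The alternatives set before the data were examined were a trim of 1% at each end of every array, quantile normalization, other shares of high and low probes, other summaries and minimum sizes of runs, a robust z scale and the use of each 5hmC array alone. Computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and plots matplotlib 3.10.9.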

Results

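DNA of wild-type mouse embryonic stem cells was enriched for 5mC or for 5hmC and hybridised to 3 arrays against genomic DNA of the same cells. The series asks where these DNA modifications lie in undifferentiated cells. There was 1 array for 5mC, 1 for 5hmC and 1 for 5hmC marked IVT, so no value has a replicate and no difference between arrays could be tested for significance. Values were present for 88735 probes on the 5mC array, 88735 on the 5hmC array and 88736 on the IVT array.

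The arrays differed in the shape of their log ratios. The 5mC array had a median of 0.24 with an SD over probes of 1.02, and its percentiles 5 and 95 were -1.40 and 1.98. The 5hmC array had a median of 0.02 and the widest middle range of the 3, with an interquartile range of 1.74 against 1.36 for 5mC and 1.495 for the IVT array. The IVT array had a median of -0.53 and an SD of 1.33. Because the centring of the deposited values is unknown, the medians carry no information on the total amount of either modification. Skewness was 0.12 for 5mC, 0.20 for 5hmC and -0.58 for the IVT array.

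The IVT array had a long lower tail of strongly depleted values, which the 5hmC array did not show relative to its own spread. Each array was judged by its own robust SD, which was 1.29 on the 5hmC array and 1.11 on the IVT array. On the IVT array 6.56% of probes lay more than 2 robust SDs below the median, that is below -2.75, against 0.098% on the 5hmC array and 1.76% on the 5mC array. A normal distribution would place 2.28% there. These 5819 probes lay together in the probe order. Where such a probe had a next-numbered neighbour, that neighbour was also depleted in 84.4% of cases (95% interval 83.1 to 85.6). They were low on the other arrays too. On the 5hmC array 85.8% of them (84.6 to 86.8) fell in the lowest 20% of probes, with a median of -1.67 against 0.10 for the remaining probes. On the 5mC array 58.8% (57.4 to 60.3) fell in the lowest 20%, with a median of -0.84 against 0.26. The 5mC array had instead a narrow peak of values. Within 0.05 of its mode at 0.27 lay 8035 probes, 3.02 times the number expected from the flanking values.

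**Figure D1:**
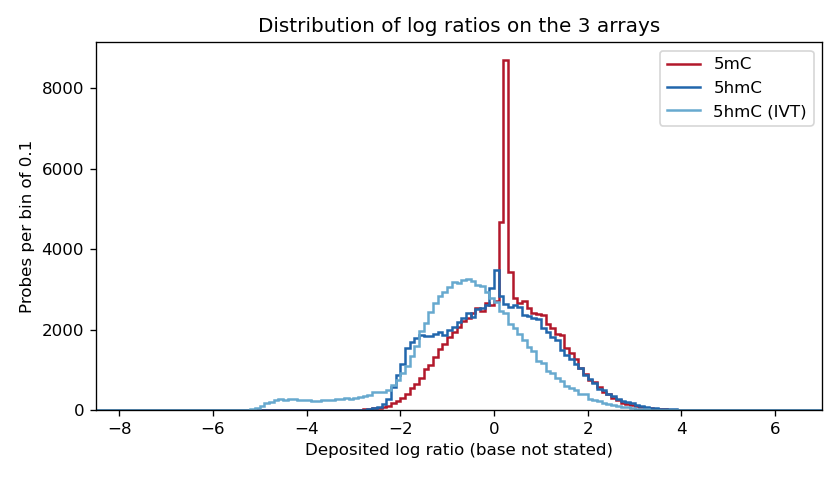
Number of probes per bin of 0.1 of the deposited log ratio (x axis, log base not stated) for the 5mC, 5hmC and IVT arrays, 1 array each. The IVT array has a long lower tail with 6.56% of its probes below -2.75, and the 5mC array has a narrow peak near 0.27.

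The first comparison was between the 5hmC arrays, which had the same source according to their labels. The arrays shared part of their pattern. Across probes r was 0.551 (0.543 to 0.559) and rho was 0.538 (0.530 to 0.545). Of the 5% of probes highest on the 5hmC array, 18.6% (17.5 to 19.8) were also among the highest 5% on the IVT array. These were 827 probes, 3.73 times the 222 expected of independent lists. At the low ends of 5% the overlap was 1341 probes or 6.05 times the number expected. The order of the ends turned at 1% of probes, where the overlap was 6.43 times the expected number for high probes and 3.83 times for low probes. The correlation was larger among probes low on the 5hmC array, and this held for every pair of arrays. Among probes below the median of the 5hmC array r was 0.516 (0.506 to 0.526), and among those above it r was 0.278 (0.265 to 0.290). For 5mC with 5hmC, a pair without the IVT array, r was 0.473 below and 0.321 above that median. For 5mC with the IVT array it was 0.299 below and 0.170 above. Of the lower group 12.6% of probes belonged to the depleted tail of the IVT array, and of the upper group 0.525%.

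The second comparison set 5mC against 5hmC in the same cells. Probes with a high 5mC log ratio tended to have a high 5hmC log ratio, and probes low on one tended to be low on the other. For the 5mC and 5hmC arrays r was 0.620 (0.614 to 0.626) and rho was 0.622 (0.616 to 0.628). For the 5mC and IVT arrays r was 0.407 (0.399 to 0.415) and rho was 0.407 (0.399 to 0.415). Of the highest 5% of 5mC probes, 25.6% (24.1 to 26.9) were among the highest 5% on the 5hmC array and 11.7% (10.7 to 12.7) on the IVT array. These overlaps of 1134 and 520 probes were 5.11 and 2.34 times those of independent lists. The overlaps at the low end were larger, at 1701 probes or 7.67 times the expected number for the 5hmC array and 910 probes or 4.10 times for the IVT array. All 3 ratios have genomic DNA of the same cells as denominator, which can add to each correlation by an amount that was not estimated. Regional base composition may also add to each correlation and was not tested. None of the 3 arrays held DNA without these modifications, so a bias shared by the precipitations could not be separated from shared modification. All 3 arrays shared 233 high and 534 low probes, where independent lists would share 11.1.

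The 5hmC log ratio rose with the 5mC log ratio over the whole range of 5mC values. From the lowest to the highest decile of 5mC probes the median on the 5hmC array went from -1.58 to 1.298, with each decile above the one before. On the IVT array it went from -1.62 to 0.16, again with each decile above the one before. The rise on the IVT array was steeper in the lower deciles of 5mC. It was 1.19 from decile 1 to decile 5 and 0.60 from decile 5 to decile 10. On the 5hmC array these steps were 1.63 and 1.25. Within a decile the probes still spread widely. The SD on the 5hmC array was 0.77 in the lowest decile and 0.97 in the highest, and it was largest in decile 5, at 1.04. On the IVT array the order of the ends was the opposite, with 1.435 in the lowest decile and 1.048 in the highest.

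**Figure D2:**
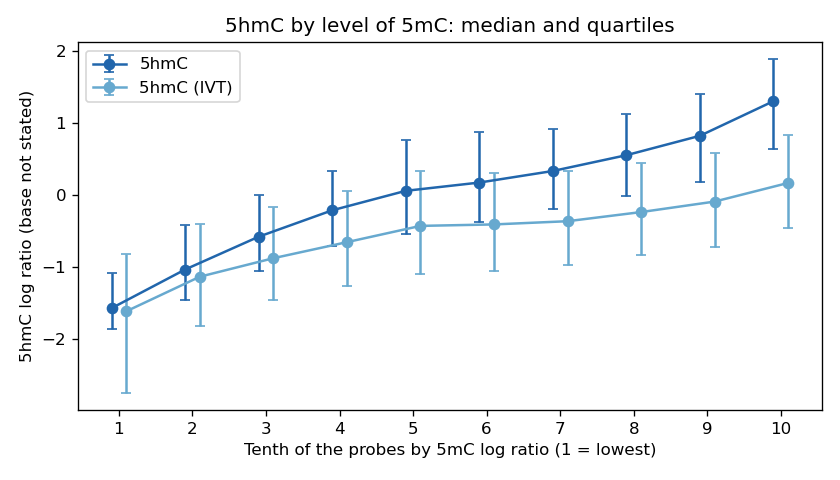
Median 5hmC log ratio (y axis, log base not stated) of the 5hmC and IVT arrays in each decile of the probes ordered by 5mC (x axis), with bars from the lower to the upper quartile of probes. The 5hmC medians rise from -1.58 to 1.298 and the IVT medians from -1.62 to 0.16.

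By correlation over all probes the 5hmC array resembled the 5mC array more than it resembled the IVT array. The r of 5mC with 5hmC exceeded the r between the 5hmC arrays by 0.070 (0.062 to 0.078). This order held among probes above the median of the 5hmC array, where the difference was 0.042 (0.026 to 0.062). It was the opposite among probes below that median, with a difference of -0.043 (-0.054 to -0.032). Among the lowest 10% of probes the order was also the opposite, with an overlap of 5.67 times that of independent lists between the 5hmC arrays and 5.09 times for 5mC with 5hmC. Among the lowest 5% and 1% it was not. There the overlap was 6.05 and 3.83 times between the 5hmC arrays and 7.67 and 15.5 times for 5mC with 5hmC. With the 5hmC array held fixed, the partial r of 5mC with the IVT array was 0.1001 (0.093 to 0.108). With 5mC held fixed, the partial r between the 5hmC arrays was 0.416 (0.409 to 0.424). With the IVT array held fixed, the partial r of 5mC with 5hmC was the largest, at 0.520 (0.513 to 0.527). These partial values are by single probes and were not scaled by the neighbour correlations, which differed between arrays. By regional correlation, given below, the IVT array was about equally close to 5mC and to 5hmC.

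Neighbouring probes showed how far the arrays agreed by region. A probe and its next-numbered neighbour correlated at 0.354 (0.344 to 0.364) on the 5mC array, at 0.743 (0.735 to 0.749) on the 5hmC array and at 0.582 (0.567 to 0.596) on the IVT array, over 61755 such pairs. Probes 50 rows apart correlated at 0.013 on the 5mC array and 0.016 on each 5hmC array. The 5mC value of a probe was thus closer to the 5hmC value of the next probe, at 0.492, than to the 5mC value of the next probe. Scaled by these neighbour correlations, the regional correlation was 0.960 (0.953 to 0.967) for 5mC with 5hmC. It was 0.680 (0.663 to 0.697) for 5mC with the IVT array and 0.671 (0.661 to 0.681) for the 5hmC arrays with each other. The last 2 values differed by 0.009 (-0.002 to 0.020). The scaling removes variation private to a probe, whether noise or a real difference between neighbours, and single arrays cannot separate these.

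**Figure D3:**
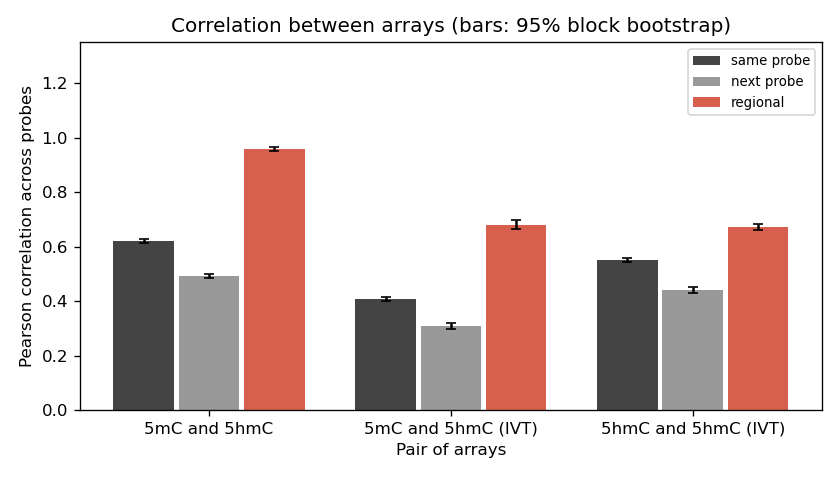
Pearson correlation across probes (y axis) for each pair of arrays (x axis), at the same probe, between a probe and the next probe, and as regional correlation, which is scaled by the neighbour correlations of both arrays. Bars show the 95% interval of the block bootstrap, and the regional value is 0.960 for 5mC with 5hmC against 0.680 and 0.671 for the other pairs.

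Runs of neighbouring probes in which the modifications ranked far apart were few. Of 14403 runs, 689 lay in the upper 20% on all 3 arrays, 5.98 times the number expected of independent arrays. A further 1598 runs lay in the lower 20% on all 3, which was 13.9 times the expected number. By the rule set beforehand, 3086 runs (21.4%) ranked higher for 5mC than for both 5hmC arrays, and 2819 (19.6%) ranked higher on both 5hmC arrays than for 5mC. Shuffling 5mC over runs gave means of 4717 and 4506. Normal values with the observed correlations gave 2920 to 3165 and 2934 to 3124, so the first count lay within the range that correlation alone gives and the second lay below it. This contrast between the directions did not hold for differences of at least 20, 30 or 40 percentile points, but it did at 50 points. The rule has no minimum size. With differences of at least 20, 30 and 40 percentile points, sizes chosen after seeing the data, the counts with 5mC higher were 1489, 758 and 353 and those with 5hmC higher 1268, 707 and 313. All 6 lay below the lowest counts of normal values, which were 1538, 835 and 355 and 1537, 826 and 348. With a difference of at least 50 percentile points, also chosen after seeing the data, the counts were 126 (0.875%) and 99 (0.687%), against 116 to 161 and 114 to 166 for normal values. The first count thus lay within the range of normal values and the second below it. At that size the counts were 129 and 155 with the 5hmC array alone and 531 and 608 with the IVT array alone.

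The run of 5 probes that starts at A_68_P32462207 had the largest difference towards 5mC. Its median 5mC was 1.09 ± 1.14 (SD over probes), at percentile 88.3. Its 5hmC was -1.48 ± 0.22 at percentile 11.7, and its IVT value was -3.95 ± 0.21 at percentile 3.50. This run lies in the last 3 blocks of the probe order, where the IVT array alone was lower, and by the 5hmC array alone its difference of 76.7 percentile points was smaller than the 80.6 of the next run. The 4 probes from A_68_P27916624 followed, with 5mC at percentile 81.6 and the 5hmC arrays at 0.941 and 3.52. The median 5mC of this run, 0.87, was smaller than the SD of 1.42 over its probes. In the opposite direction the 3 probes from A_68_P23230625 had 5mC at percentile 11.8 and the 5hmC arrays at 82.9 and 95.2. Their 5mC was -0.75 ± 0.20, their 5hmC 1.07 ± 0.99 and their IVT value 0.74 ± 1.45. The 3 probes from A_68_P28875979 had 5mC at percentile 21.0 and the 5hmC arrays at 96.8 and 92.1. Their 5mC was -0.38 ± 0.41, their 5hmC 1.86 ± 0.60 and their IVT value 0.56 ± 0.84, so the SDs of 5mC and IVT exceeded the size of the medians. By the 5hmC array alone the difference of this run, -75.8 percentile points, was larger in size than the -71.1 of the run from A_68_P23230625.

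Along the probe numbers the medians of the last blocks of the IVT array stood apart from those of its other blocks. On the 5mC and 5hmC arrays the medians of the same blocks did not. Over the first 86 blocks of 1000 probes the block median of the IVT array was -0.52 ± 0.10 (SD over blocks), with a range from -0.82 to -0.28. In the last 3 blocks, which hold 2734 probes, the medians lay between -1.01 and -0.88. The 5mC array had medians of 0.28, 0.26 and 0.25 there, within its range of 0.13 to 0.31 elsewhere. The 5hmC array had 0.19, 0.01 and 0.03, within its range of -0.32 to 0.34. Among the first 86 blocks, block 63 had the lowest median on each of the 3 arrays, at -3.49, -2.77 and -3.11 SD from the mean of these blocks for 5mC, 5hmC and the IVT array.

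**Figure D4:**
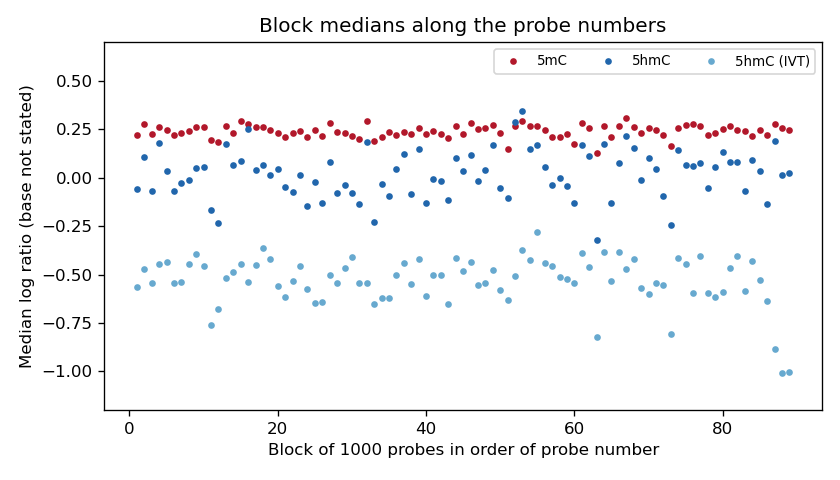
Median log ratio (y axis, log base not stated) of each block of 1000 probes in order of probe number (x axis) on the 5mC, 5hmC and IVT arrays. The last 3 IVT blocks, between -1.01 and -0.88, lie below the other 86, which range from -0.82 to -0.28.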

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

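No correlation changed sign under the alternatives given here. The excess of the r of 5mC with 5hmC over the r between the 5hmC arrays stayed above 0 under these alternatives but was -0.043 (-0.054 to -0.032) among probes below the median of the 5hmC array. The difference between 5mC and 5hmC in correlation with the IVT array was -0.144 (-0.149 to -0.138) for r and 0.009 (-0.002 to 0.020) for the regional correlation. Of the alternatives, 23 of 71 values stayed within the interval of the main value or, for counts of runs, within 1.5 times the main count. Runs in place of genes, the alternatives with run medians, ranks, neighbours at a distance of 2 numbers and left-out probes, minimum differences between percentiles, the difference between correlations and the regional correlation with all their alternatives, and quantile normalization for the 5hmC arrays were chosen after seeing the data. The r of 5mC with 5hmC, of 5mC with the IVT array and between the 5hmC arrays was 0.599, 0.378 and 0.520 within the central 98% of every array, 0.778, 0.546 and 0.638 over medians of runs, and 0.646, 0.425 and 0.563 without the 5mC peak. The last of these was 0.560 after quantile normalization and 0.538 on ranks. The excess of the first over the last was 0.080, 0.141 and 0.083 in the first 3 of these settings and 0.085 on ranks. Overlaps of high probes over independent lists were 8.80 and 3.60 at 1% and 10% for 5mC with 5hmC, 4.06 and 2.06 for 5mC with the IVT array, and 6.43 and 2.82 between the 5hmC arrays. For low probes they were 15.5 and 5.09, 4.74 and 3.73, and between the 5hmC arrays 3.83 and 5.67. At 10% of low probes the overlap between the 5hmC arrays thus exceeded that of 5mC with 5hmC, against the order at 1% and 5%. Low probes thus overlapped less than high probes between the 5hmC arrays at 1%, against the order at 5%, and the cause was not tested. A stricter share holds fewer probes and its ratio can reach higher values. The regional correlations in the same order were 0.967, 0.751 and 0.730 on ranks and 0.979, 0.725 and 0.702 with probes 2 numbers apart. Runs with 5mC above 5hmC, 3086 of 14403 in the main setting, numbered 5853 of 26979 with a minimum of 1 probe and 1343 of 6449 with a minimum of 5, and runs with 5hmC above 5mC, 2819 in the main setting, numbered 5406 and 1195, since the minimum sets how many runs there are. With the 5hmC array alone they numbered 7206 and 7193 and with the IVT array alone 7208 and 7195, since no second array then limits them, and runs with equal percentiles count in neither direction. Without a minimum difference these counts ask only which percentile is higher. Percentiles are spread alike on every array, so a near-even split is built in and says little about the modifications. With differences of at least 20, 30, 40 and 50 percentile points, which keep fewer runs by construction, the counts were 1489, 758, 353 and 126 for 5mC above 5hmC and 1268, 707, 313 and 99 for 5hmC above 5mC. The cause of the other shifts was not tested. Alternatives by gene medians, gene lists, probes with several gene names and chromosome had been listed beforehand and were not run, because genes and positions were not used here. Leaving out a replicate was not possible with 1 array per group, and signal over background is unknown. No paired analysis was possible because each group holds 1 array.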

Other observations

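All tests of explanations were chosen after the patterns were seen, and the rules for reading 2 of them, on one shift of the ratio and on values unrelated to the DNA, were rewritten after a first version had counted against both explanations. The last 3 blocks of probe numbers also differed in how the 5mC and 5hmC arrays related to each other. The r of 5mC with 5hmC was 0.392, 0.460 and 0.493 in these blocks, below the range of 0.507 to 0.713 in the other 86. Probes in the lowest quintile of the 5hmC array had a median 5mC of -0.52 there against -0.85 elsewhere, and probes in its highest quintile had 0.72 against 1.11. The range of the 5mC log ratio between the lowest and the highest quintile of the 5hmC array was therefore narrower in these blocks. The r of 5mC with the IVT array was 0.292, 0.315 and 0.293 there, within the range of 0.274 to 0.508 elsewhere, and 0.3002 (0.256 to 0.338) over the 3 blocks together against 0.411 (0.402 to 0.419) elsewhere. Between the 5hmC arrays r was 0.473, 0.548 and 0.526, within the range of 0.449 to 0.669 elsewhere.

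The first pattern is that the 5hmC array was closer to the 5mC array than to the IVT array, which has the same stated source. Independent noise of single probes was argued against, since the difference of regional correlations, from which such noise and any other variation private to a probe cancels, was 0.289 (0.277 to 0.301). The depleted tail of the IVT array was argued against as the whole cause. The difference of r was 0.042 among probes above the median of the 5hmC array, where that tail is rare. Below that median, where 12.6% of probes belonged to the tail, the difference was -0.043, which is opposite to the pattern. An exchange of the labels of the 5mC and IVT arrays may also give this pattern: the IVT array had about the same regional correlation with 5mC, 0.680, as with 5hmC, 0.671, while by single probes it was closer to 5hmC, with an r of 0.551 against 0.407. Without a probe of known position no value decides it, and regional base composition, the procedure behind the word IVT and a true likeness of 5mC and 5hmC stay open as untested.

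The second pattern is the drop of the IVT array in the last 3 blocks. Less 5hmC in both precipitations was argued against, since the 5hmC array there stood 0.47 SD above its mean over the other blocks. That value restates the 5hmC block medians with which the pattern was described, so it is not separate evidence. One shift of the ratio for all these probes was left undecided. The shift was -0.56, -0.58, -0.52 and -0.45 in the upper 4 quintiles of the 5hmC array and -0.22 (-0.51 to 0.06) in the lowest, where the depleted tail lies. No single value lay within every interval, since that of quintile 3 ran from -0.668 to -0.526 and that of the lowest began at -0.513. The condition set for one shift was thus narrowly missed, and the wide interval of the lowest quintile did not meet the condition against it. Drift along the probe numbers was not tested, since these blocks were singled out for their low values. Whether these probes lie on a single chromosome is unknown, because positions were not used here. A property of that stretch of the genome therefore cannot be told apart from a technical cause.

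The third pattern is the narrow peak of the 5mC array, with about 5372 probes, 6.05% of all, beyond those expected from the flanks. Islands with 1 common level of methylation were argued against, since the next probe of a probe in the peak was in the peak in 9.47% of cases and that of a flanking probe in 8.87%, a difference of 0.601 percentage points (-0.393 to 1.66), and in the window from 0.20 to 0.28 that was tried first the difference was -0.305 (-1.25 to 0.585). Values unrelated to the DNA at those probes may account for part of the peak. The SD of 5hmC was 1.07 (1.05 to 1.08) in the peak, above 0.94 in the flanks. It was below the 1.11 predicted if the excess over the flanks, 66.9% of the window, were unrelated to 5hmC. That figure rests on an assumed mixture in which the remaining probes resemble the flanks. The condition set for this explanation, an interval that holds the predicted SD, was thus not met. The condition against it, an SD no higher than in the flanks, was not met either, so the explanation was left undecided. In the window tried first the SD was 1.09. A smaller excess stood on the 5hmC array, with 3490 probes within 0.05 of its mode at 0.01 against 2581 expected, and signal intensities that would show whether both channels were equal there were not used here.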
